A study of Mus musculus with 2 samples.

How the data were processed

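RNA from 1 mock-transfected and 1 IL10RB-transfected culture of NHOS mouse osteosarcoma cells was extracted with an RNeasy kit and made into cDNA libraries with the SMART-Seq v4 Ultra Low Input kit, per the labels' protocols. Cells grew in DMEM with serum and G418, per the labels. The submitters' processing notes name DRAGEN, without a version or role. The aligner settings, genome build and annotation version are not given in the sources used here. The start and end of the genes are printed as the deposited table gives them. They are not those of GRCm38, since only 1546 of 52133 gene identifiers shared with a GRCm38 annotation had the same start and end.

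The deposited table lists, per the file headers, an estimated count and a TPM value for each gene in each library, with gene length and names of Reactome pathways. The authors' estimated counts are not normalised, and 11.0% of genes in each library had a fractional count, as arises when reads are shared between genes. The deposited TPM values are scaled for gene length and depth by the authors' pipeline. Gene length is given in bases, per the file headers, and the log2 folds here were computed from the deposited counts. Kits of this type amplify cDNA without molecular identifiers in the files used here, so reads are not independent molecules and intervals cover counting error only. Strand was not stated, so reads of overlapping and antisense genes cannot be separated.

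Estimated counts were rounded to whole numbers. They summed to 18766040 (mock) and 23898112 (transfectant). Scaling used TMM factors of 0.983 and 1.02 from edgeR 4.0.16 in R 4.3.3, and DESeq2 1.42.0 gave the size factors of an alternative. Neither tool was used for a test. After scaling, 1 count equalled 0.0542 CPM in mock and 0.0411 CPM in the transfectant, and the floor of 3 counts for a value of 0 was 0.163 and 0.123 CPM. The log2 fold was that of CPM plus a pseudocount of 0.5, transfectant over mock, which understates differences of low genes. A gene entered the counts of higher and lower genes with at least 50 counts in 1 library, and was called at a fold of 2 on that scale. Folds printed in the text are ratios of CPM without the pseudocount, with exact conditional (Clopper-Pearson) 95% intervals, and levels carry exact Poisson intervals. Where 1 library had 0 counts, a fold given as at least a value uses the floor of 3 counts. The bound of the exact interval is less extreme, at 264-fold against 325-fold for Arhgap36. Other calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

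With 1 library per group no p-value was computed. Gene lists, the rule for naming genes and all alternatives except those named as added were fixed before the data were examined. The 36 lists held 790 genes. For each list with at least 5 members past the floor, the median log2 fold was placed among 10000 random lists of the same size matched on mean expression in 20 bins, which describes these libraries and does not test the conditions. Named genes were Il10rb, the 12 highest and 12 lowest by log2 fold among genes with a mean of at least 10 CPM and a symbol that is not a predicted model, and up to 4 members of each list with the largest absolute log2 fold. Any member of the receptor, JAK-STAT and immune lists could be given, and other names were chosen after their values were seen. These are the neighbours of Il10rb, the lower members of the antigen presentation list, Cebpd and marker genes under the floor. Not every gene that the rule names is reported here.

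The procedure was tested on simulated counts of this comparison, in which 100 of 100 genes seeded at 3-fold and 100 of 100 at 6-fold were recovered, 0 of 11442 unchanged genes were called, and intervals covered the true ratio in 95.3% of 11642 genes. The simulation holds counting noise only. Alternatives were other scalings (DESeq2 size factors, total counts, upper quartile), pseudocounts of 0.1 and 2, no floor and a floor of 200, folds of 1.5 and 4, calls by the counting interval, protein coding genes, no predicted models and the deposited TPM. A subtraction of background reads per kb and a centring within 10 bins of gene length and 10 of transcript GC content were added after seeing the data. GC content came from GRCm38 transcripts, with a value for 99.8% of genes past the floor.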

Results

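RNA sequencing compared NHOS cells, a mouse osteosarcoma line, after mock transfection and after transfection with IL10RB, which encodes the beta chain shared by the receptors for interleukin-10 and related cytokines. The comparison asks which transcripts differ in level when the receptor chain is introduced. There was 1 library per group, so no test, p-value or SD between replicates could be had, and every difference below is between 2 libraries and has no replicate check. The estimated counts summed to 18766040 in the mock library and 23898112 in the transfectant library, over 55414 listed genes. Intervals given with values are exact 95% intervals and cover counting error only. Counts were scaled for library size to CPM, and folds are ratios of CPM.

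Il10rb itself was 2.57-fold higher in the transfectant library (95% counting interval 2.32 to 2.85), which matches the direction of the labels. Its level was 26.2 CPM in mock (23.9 to 28.7, from 484 counts) and 67.5 CPM in the transfectant (64.3 to 70.9, from 1641 counts). The deposited TPM values were 18.4 and 49.8. The gene (ENSMUSG00000022969.14) lies on the plus strand of chromosome 16 from 91203052 to 91222722, as the deposited table gives it, with the genome build not given in the sources used here. The labels do not state the species of the construct, so the mouse gene's count may or may not include construct reads, and the mock library already carried Il10rb transcripts. Of the 14 genes for IL-10 family ligands and receptors, Il10rb alone had at least 50 counts in a library, with Il10ra, the ligand-binding chain of the IL-10 receptor, at 3 counts in mock and 0 in the transfectant and Il20rb at 30 and 15.

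Among 21 neighbouring genes measured from 700 kb before to 1000 kb after Il10rb, 4 were at least 2-fold higher and the median log2 fold was 0.24. Those 4 are close to the general share, since 19.7% of all genes past the floor were at least 2-fold higher. The median log2 fold of all genes past the floor was 0.07. The interferon receptor genes Ifnar2 and Ifnar1 on either side were within 2-fold, at ratios of 1.09 (1.01 to 1.18) and 0.912 (0.851 to 0.977). Ifngr2, which encodes the interferon-gamma receptor's second chain, was 2.47-fold higher at 121 kb, and Tmem50b 2.24-fold higher at 149 kb. Dnajc28 and Mrps6 were the other genes past 2-fold in the higher direction, and Urb1 was 2.06-fold lower. Among protein coding genes with at least 100 counts in both libraries, 215 of 309 on chromosome 16 were higher, with a median log2 fold of 0.41 against -0.14 to 0.09 for the central 95% of permutations of genes among chromosomes. Chromosome 16 was not alone, since 11 of 20 chromosomes lay outside their permuted range and chromosome 12 lay further from 0, at -0.44. The window of 25 genes that starts with Il10rb had a median of 0.56.

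**Figure D1:**
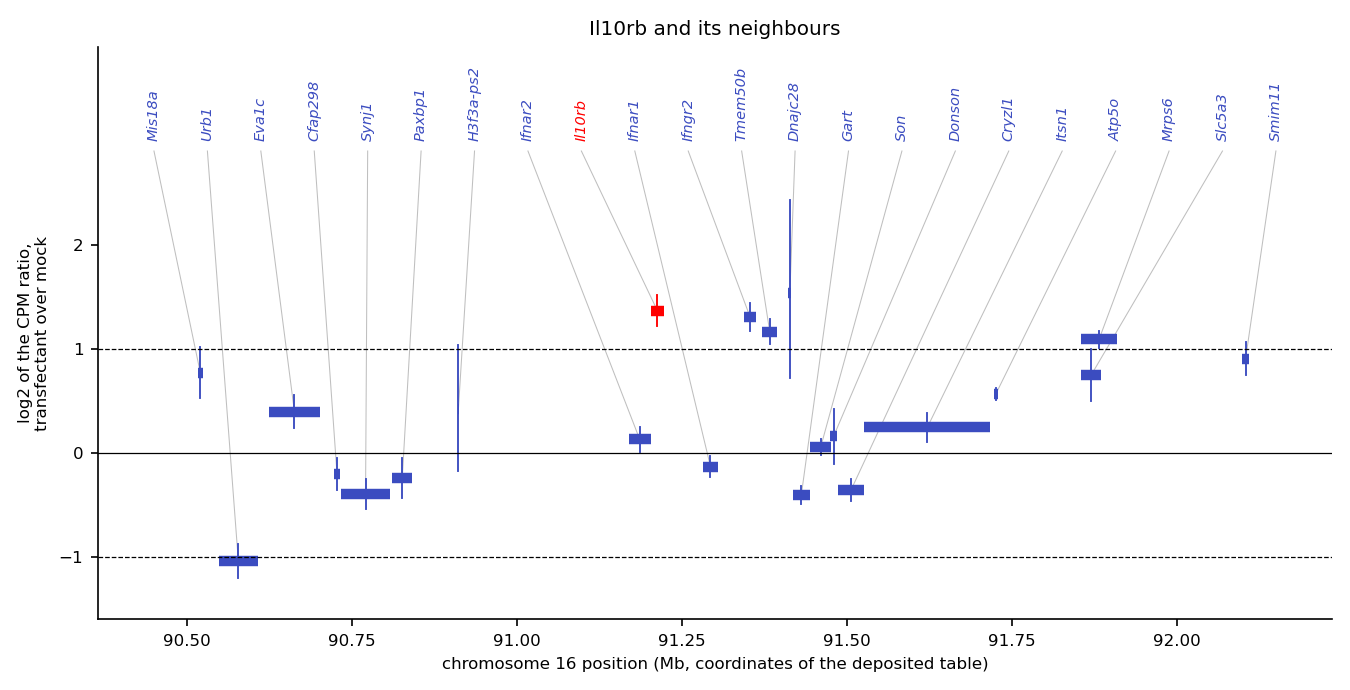
Map of Il10rb and its neighbours on chromosome 16, with position in Mb on the x axis and the log2 ratio of CPM, transfectant over mock, on the y axis. Thick horizontal bars span each gene, thin vertical lines are 95% counting intervals, the dashed lines mark 2-fold, and Il10rb, at 2.57-fold, stands above Ifnar2 (1.09) and Ifnar1 (0.912) beside it. Dnajc28 (2.89, from 16 counts in mock and 61 in the transfectant) lies higher than Il10rb, and Ifngr2 (2.47) lies close to it.

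Across the transcriptome, 2359 of 11952 genes with at least 50 counts in a library (19.7%) were at least 2-fold higher in the transfectant and 1419 (11.9%) at least 2-fold lower. The log2 CPM of the 2 libraries correlated at r = 0.856 across genes, which are not independent replicates. Among the 12 highest genes by the rule for named genes were Arhgap36, the aldehyde dehydrogenase Aldh3a1 and the imprinted gene Mest. Among the 12 lowest were the neutral amino acid transporter Slc6a15 and the stress-responsive pseudokinase Trib3. Arhgap36 had 0 counts in mock and 1286 in the transfectant, at least 325-fold higher when mock is set at 3 counts. Aldh3a1 was at 2.22 CPM in mock and 230 CPM in the transfectant, a 104-fold difference (76.3 to 145). Mest was at 12.6 and 663 CPM, 52.7-fold apart (46.3 to 60.3). Pdzk1ip1 and Acss3 were likewise at 0 counts in mock and at least 169-fold and 158-fold higher. Cox7b2 rested on 1 count in mock against 783, and F13a1, the coagulation factor XIII A subunit, on 4 against 911. The remaining genes of the 12 highest also rested on few counts in mock, so their folds have wide intervals. They were the ferritin receptor Scara5 (149-fold, 75.4 to 346), Dglucy (156-fold, 75.5 to 388) and the selenium carrier Selenop (99.5-fold, 58.0 to 187). The glutathione transferase Gstm2 (79.6-fold, 51.4 to 131) and Fhl1 (73.8-fold, 47.1 to 123) completed them.

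In the lower direction, Slc6a15 was at 163 CPM in mock and 1.40 CPM in the transfectant, 117-fold lower (83.4 to 169). Car6 had 490 counts in mock and 0 in the transfectant, at least 215-fold lower, and Avil had 636 counts against 1. The inositol phosphate synthase Isyna1 was 72.0-fold lower (52.7 to 101) and the basal keratin Krt14 was 99.1-fold lower (53.6 to 207). Slc7a11, the cystine transporter, was 23.1-fold lower (18.5 to 29.2) and Trib3 was 18.7-fold lower (17.3 to 20.2). Rspo1, an enhancer of Wnt signalling, was 21.1-fold lower, Ngef 19.7-fold and Syt13 36.1-fold. Dynap and Gdpd1 completed the 12 lowest at 14.4-fold and 14.1-fold.

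Genes of interferon and antigen presentation stood on the higher side. Of 38 interferon-stimulated genes, 30 were at least 2-fold higher and 1 at least 2-fold lower, with a median log2 fold of 1.85 that exceeded 10000 of 10000 random lists matched on expression. Lgals3bp was 16.3-fold higher, the guanosine triphosphatase Igtp 20.5-fold and Ifi27l2a 31.8-fold. Trim30a had 2 counts in mock and 352 in the transfectant, and Iigp1, at 0 counts in mock, was at least 50.8-fold higher. Of 22 genes of MHC class I antigen presentation, 16 were at least 2-fold higher and 2 lower, with a median of 1.41, above 10000 of 10000 random lists. The immunoproteasome subunits Psmb8 (13.6-fold, 12.6 to 14.8) and Psmb9 (8.55-fold), the peptide loader Tapbp (5.15-fold) and the class I gene H2-T22 (7.20-fold) led this list. The lower members were the endoplasmic reticulum chaperones Calr, which is also on the unfolded protein response list, and Pdia3. Several of these genes share reads with close copies, and fractional counts marked 33.6% of genes past the floor, so the split between paralogs is uncertain. Reactome pathways on the same themes, looked at afterwards, shifted less than these lists. Interferon alpha/beta signalling had 3 higher and 1 lower of 11 (median 0.24, above 719 of 1000 random lists). Folding, assembly and peptide loading of class I had 13 higher and 6 lower of 28 (median 0.74, above 1000 of 1000).

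Signalling lists were mixed. Among 11 JAK-STAT kinases and transducers, 2 were at least 2-fold higher, Stat5a (2.55-fold, 2.23 to 2.93) among them, and 0 lower, for a median of 0.62, above 9687 of 10000 random lists. Of 23 STAT3 response genes, 8 were at least 2-fold lower and 1 higher, with a median of -0.72 that was above only 8 of the 10000 random lists. The kinase Pim1 was 8.30-fold lower, Il4ra 6.15-fold, Fosl1 5.83-fold and the growth regulator Myc 5.45-fold, whereas Cebpd was 3.99-fold higher. Among 17 inflammatory cytokines and chemokines, 10 were higher and 3 lower by at least 2-fold, with a median of 1.43 above 9925 random lists, which was 0.91 with a pseudocount of 2 and 2.13 with a floor of 200 counts. Il18 was 25.8-fold and the monocyte chemoattractant Ccl2 18.6-fold higher, Ccl7 had 3 counts against 148, and Lif was 10.7-fold lower. Of 16 NF-kappaB response genes, 5 were higher and 2 lower, and the median (-0.05, with -0.49 in the deposited TPM and -0.40 with a floor of 200 counts) and the mean (0.39) differed in sign. Ccl2, Vcam1 (25.6-fold) and Birc3 (4.05-fold) were higher and Ptgs2 3.44-fold lower. The 15 immune inhibitory ligands and factors split 3 higher to 3 lower (median 0.14), with Lgals9 21.2-fold higher, Vsir at 0 counts against 94 and at least 23.8-fold higher, and Cd274, which encodes PD-L1, 4.67-fold lower.

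**Figure D2:**
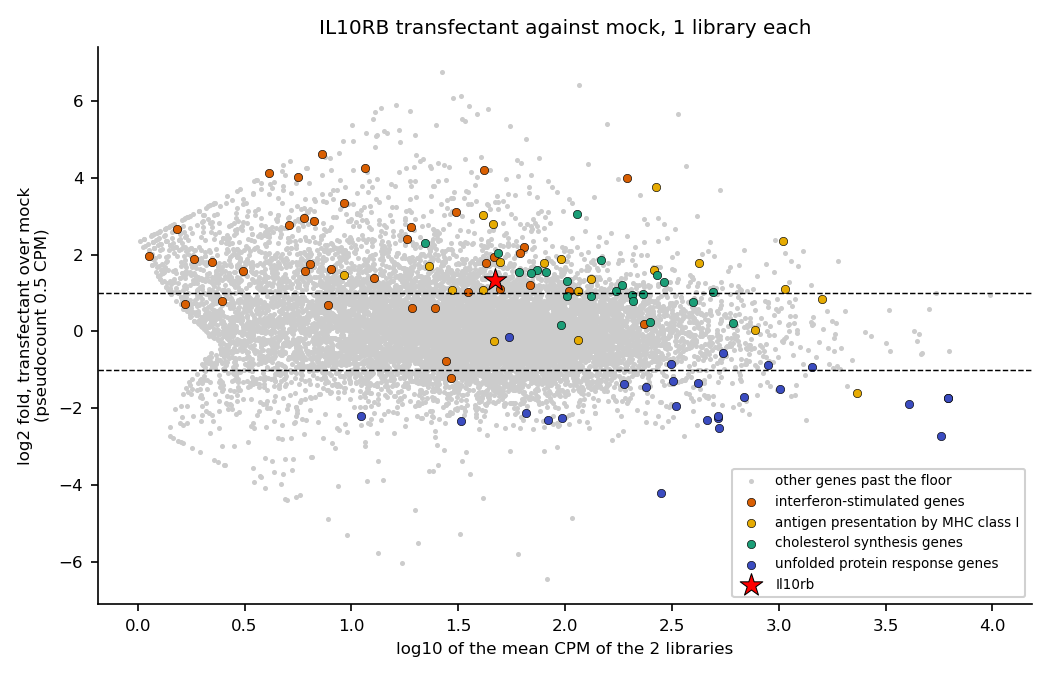
Log2 fold (transfectant over mock, y axis) against the log10 of the mean CPM of the 2 libraries (x axis) for the 11952 genes past the floor, with a pseudocount of 0.5 CPM and dashed lines at 2-fold. Members of 4 gene lists are coloured and Il10rb is a star; the interferon-stimulated genes (median 1.85) lie mostly above the upper line and the unfolded protein response genes (median -1.88) mostly below the lower line.

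Genes of the unfolded protein response, which act in protein folding and stress in the endoplasmic reticulum, were lower together. Of 25 such genes, 20 were at least 2-fold lower and 0 higher, and the median of -1.88 lay below all 10000 random lists. Trib3 led the list, followed by the chaperone Hspa5, which was at 9924 CPM in mock and 1520 CPM in the transfectant and was 6.53-fold lower. Hyou1 was 5.69-fold and Dnajb9 5.17-fold lower. Cholesterol synthesis genes went the other way. Of 23, 14 were at least 2-fold higher and 0 lower, with a median of 1.22 above 10000 random lists, led by Mvk (8.50-fold), Tm7sf2 (5.19-fold), Dhcr7 (4.18-fold) and Idi1 (3.67-fold).

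Bone and matrix genes tended towards higher levels in the transfectant. Of 18 osteoblast lineage markers, 8 were higher and 2 lower by at least 2-fold (median 0.68, above 9968 random lists), including bone sialoprotein Ibsp (8.86-fold), the osteocalcin genes Bglap (5.64-fold) and Bglap2 (5.07-fold) and Omd (4.84-fold). Among 22 collagens and related matrix genes 8 were higher and 2 lower (median 0.66, above 9985), with Col18a1 9.21-fold, Col8a1 7.98-fold, Lum 5.48-fold and Postn 5.42-fold higher. Matrix proteases and inhibitors counted 9 higher and 0 lower of 19 (median 0.99, above 9996), with the collagenase Mmp13 14.5-fold, Mmp15 7.21-fold and the inhibitor Timp2 3.54-fold higher. The 12 osteoclast regulators split 5 to 4 (median 0.04, ranging from -0.08 with upper quartile scaling to 0.56 in the deposited TPM). Osteoprotegerin, Tnfrsf11b, was 69.5-fold higher (40.5 to 131), Wnt5a 11.7-fold and Sema3a 7.86-fold higher, and Lif lower as above. Of 26 TGF-beta and BMP signalling genes 6 were higher and 1 lower (median 0.30), with Tgfbr3 8.84-fold and Fstl1 5.12-fold higher and Skil 6.04-fold lower. The 15 Wnt feedback and target genes had 5 higher and 3 lower (median 0.28), Nkd2 at 5.49-fold higher among them.

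Lineage and tumour-associated lists were less uniform. Of 16 epithelial-mesenchymal transition genes 4 were higher and 2 lower (median 0.15), with S100a4 11.8-fold, Acta2 4.28-fold and Tagln 3.89-fold higher and Zeb1 2.80-fold lower. Among 12 stem cell and tumour-initiating cell markers 5 were higher and 2 lower (median 0.23), Aldh3a1 and Ly6a (10.5-fold) leading, with Myc lower. For 14 angiogenic factors the split was 4 to 1 (median 0.22, and slightly below 0 after centring by gene length and GC content), with Thbs2 4.12-fold higher, Vegfa 2.45-fold lower and Angpt1 at 3 counts against 202. Of 19 p53 target genes, 6 were higher and 3 lower (median 0.42), with Trp53inp1 6.16-fold and Btg2 5.93-fold higher and the cell cycle inhibitor Cdkn1a 9.30-fold lower.

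Proliferation and metabolism lists went in both directions. Of 32 DNA replication genes 8 were higher and 0 lower (median 0.54, above 9982 random lists), led by thymidine kinase Tk1 (14.2-fold), Rrm2 (3.25-fold) and Tyms (2.67-fold). G2 and mitosis genes had 2 higher and 0 lower of 30, with a median of -0.04 that was positive with total count scaling. Glycolysis and hypoxia genes had 1 higher and 6 lower of 31 (median -0.22), with Hk2 3.88-fold and Ero1a 3.57-fold lower. Nuclear-encoded respiratory chain genes had 2 higher and 0 lower of 35 (median 0.20, and -0.02 after centring by gene length and GC content), the highest being Ndufa4 at 2.14-fold, and the 13 mitochondrially encoded transcripts were all within 2-fold (median 0.43). The 22 oxidative stress genes split 3 higher to 6 lower, and their median (0.10, negative with upper quartile scaling) and mean (-0.28) differed in sign. Nqo1 was 6.78-fold higher, and haem oxygenase Hmox1 5.66-fold and Gclm 4.22-fold lower. Cytosolic ribosomal protein genes had 0 higher and 2 lower of 45 (median -0.50, above only 7 of 10000 random lists), led by Rpl34 at 2.26-fold lower, and share reads with many pseudogenes.

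**Figure D3:**
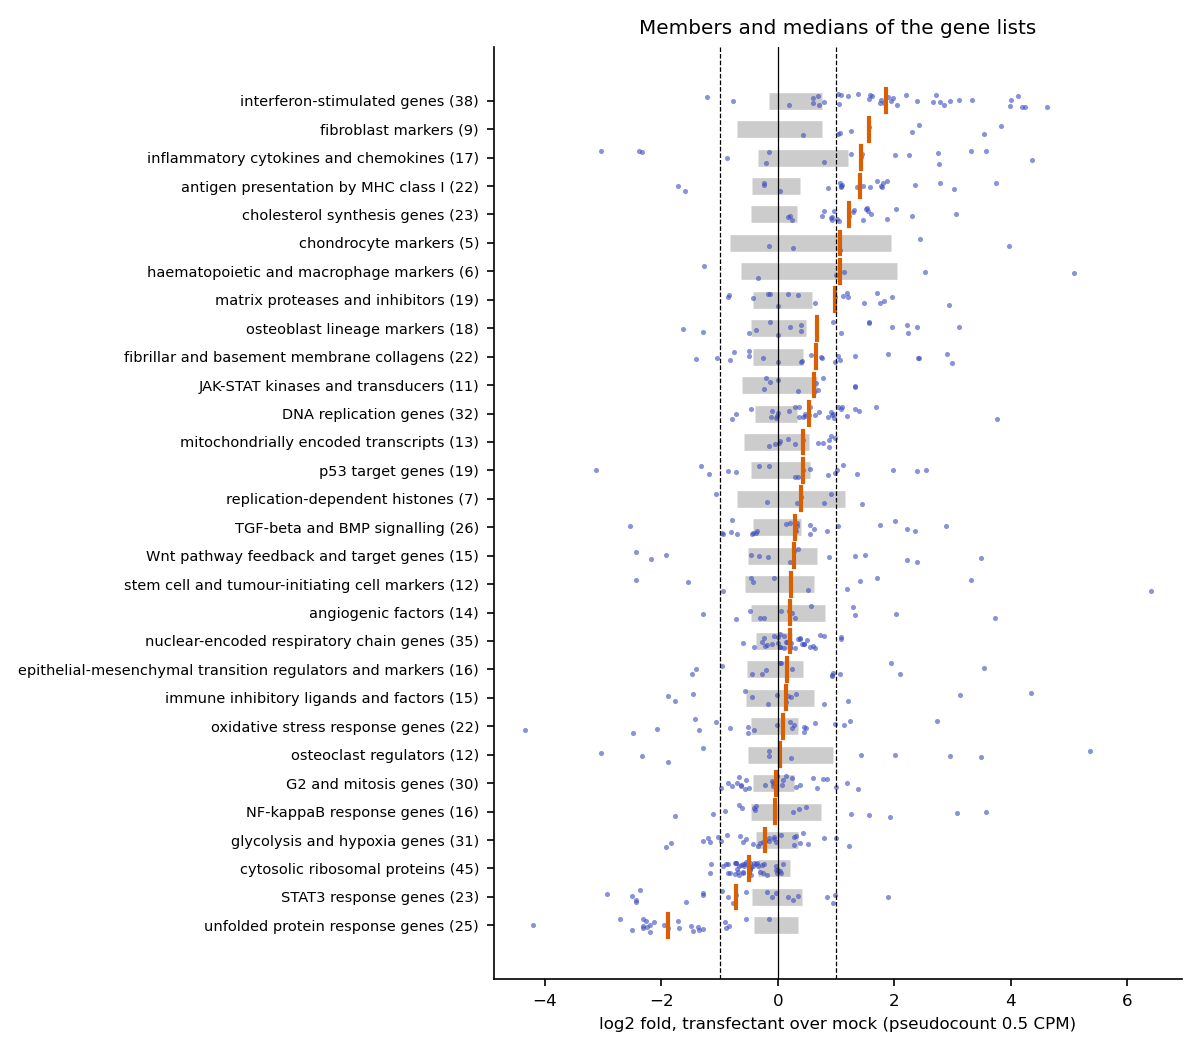
Log2 fold (transfectant over mock, x axis) of the members past the floor of each gene list with at least 5 such members; blue points are genes, orange ticks are medians, grey bars hold the central 95% of medians of 10000 random lists, dashed lines mark 2-fold, and the number of genes stands in brackets. The medians run from -1.88 for unfolded protein response genes to 1.85 for interferon-stimulated genes.

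Marker transcripts of other cell types were examined beside these lists. Of 9 fibroblast markers, 8 were at least 2-fold higher and 0 lower (median 1.56, above 9998 random lists), with Ly6c1 18.6-fold and Pdgfra 5.13-fold higher, and S100a4, Lum, Pdpn, Col3a1 and Dcn are also on the lists above. Haematopoietic and macrophage markers had 6 of 23 past the floor, 3 higher and 1 lower. Lyz2 was at 5 counts against 626 and Cd68 at 12 against 150, whereas the pan-leukocyte gene Ptprc had 27 counts in mock and 0 in the transfectant and Tyrobp had 0 in both. Chondrocyte markers had 5 past the floor, 3 of them higher, with Comp 22.2-fold and Matn3 13.7-fold. Endothelial markers had 2 higher (Flt1, 2.84-fold, and Egfl7, 2.18-fold) and 1 lower (Esam, 3.89-fold), muscle markers 2 higher (Acta1, 6.30-fold, and Des, 5.52-fold), epithelial markers only Krt14, and adipocyte markers 0 past the floor. Among library quality lists, 7 replication-dependent histone genes split 1 higher (H1f5, 3.51-fold) to 1 lower (H2bc4, 2.12-fold), and of 3 nuclear-retained RNAs Neat1 was 2.36-fold lower and Malat1 at a ratio of 0.909.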

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

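The background and length and GC alternatives were chosen after seeing the data. Il10rb kept its direction and side of the threshold in 8 alternatives, at log2 folds of 1.23 to 1.40. Without a floor 2316 genes were lower, since genes with few counts enter. At a fold of 1.5, 3666 were higher and 2853 lower, and at a fold of 4 there were 772 and 219, as the threshold itself sets. The other 25 counts of calls, which include that of higher genes without a floor, moved by less than 1.5 times. Upper quartile scaling put the median of genes past the floor at -0.04 against 0.07 and gave 2056 higher and 1755 lower. Over all lists and alternatives together, 268 values of list medians moved by less than their spread and 2 did not. Lists with few genes past the floor could move far within it. The haematopoietic marker median ran from 0.57 to 3.04 and the chondrocyte marker median from 0.70 to 1.91. The interferon-stimulated median was 1.31 with a pseudocount of 2, and the respiratory chain median was -0.02 after length and GC centring, where the cause was not tested. Medians near 0 of the osteoclast, oxidative stress, mitosis and angiogenic lists changed sign under scaling or centring. For the named highest and lowest genes, 101 values lay outside the counting interval and 91 within it, and none changed direction. That interval is of the ratio without a pseudocount. Genes with few counts in 1 library, such as Arhgap36, were already outside it in the main setting. The split therefore does not measure how far these genes depend on the processing. No paired analysis was possible because each group had 1 library. Depth limits genes near the floor: 1 count was 0.0542 CPM in mock and 0.0411 in the transfectant.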

Other observations

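The gene groups in this paragraph were chosen after their values were seen. Picked genes for tRNA synthetases, amino acid synthesis and amino acid transport were lower in the transfectant library: 25 of 30 were at least 2-fold lower and 0 higher, with a median log2 fold of -1.81. Wider Reactome pathways were less uniform. Amino acid transport across the plasma membrane had 9 lower and 3 higher of 18 (median -0.89). Metabolism of amino acids and derivatives had 15 lower and 24 higher of 109 (median 0.20). Examples of the picked genes are Aldh1l2, Gpt2 and Eprs, a mitochondrial folate enzyme, an alanine aminotransferase and a tRNA synthetase. Picked genes of xenobiotic metabolism were higher, 13 of 19 by at least 2-fold against 3 lower, with a median of 1.88, led by Aldh3a1, Gstm2 and Ephx1. Wider Reactome pathways shifted less. Biological oxidations had 32 higher and 9 lower of 78 (median 0.75), and glutathione conjugation 6 higher and 4 lower of 21 (median 0.41). Of 9 interferon receptors and regulators past the floor, 5 were higher and 1 lower (median 1.19), with Irf7 at 101 counts against 750 and Sting1 at 375 against 1790, while Ifnb1, the interferon beta gene, had 2 counts in mock and 0 in the transfectant. The wider Reactome pathway of interferon signalling had 10 higher and 3 lower of 34, with a median of 0.12 above 683 of 1000 random lists. Among the 573 Reactome pathways screened here, those with 10 to 150 genes past the floor and a pathway name that could be used, rRNA processing had the lowest median (-1.01), with 38 of 74 genes at least 2-fold lower. The highest medians within the same limits were those of scavenger receptor ligand uptake (1.93, 10 genes), laminin interactions (1.70, 11 genes) and striated muscle contraction (1.55, 11 genes).

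Of the tests that follow, those on receptor-gene reads, on the unfolded protein response and on the interferon list were chosen after the result was seen, and those on chromosome position were written before. The spread used to judge the held-out genes was added once their values were known.

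The mock library held reads in receptor genes that are expressed in sensory neurons. Of 1412 olfactory receptor genes, 510 were above 0 in mock and 39 in the transfectant. Sequencing depth is argued against as the cause, since the mock library, with more such genes above 0, was the shallower at 0.785 of the transfectant's total. Genomic DNA carry-over is a candidate source, since reads per kb in mock were 0.559 (0.535 to 0.583) for olfactory and 0.572 (0.537 to 0.608) for vomeronasal receptors. The ratio was 1.02, and transcription would not require equal rates. The 8 single-copy Y-linked genes had 0 counts against 13.7 expected at a trimmed rate of 0.382 reads per kb, which leaves out the genes with the most reads. That goes against DNA carry-over unless the line has no Y chromosome, which was not established here. Against even DNA coverage, evenly spread reads at the untrimmed olfactory rate of 0.559 per kb would have put 972 of the olfactory receptor genes above 0. That rate includes the genes with the most reads, and the expected number was not computed at the trimmed rate. Low-level transcription, copies made in amplification and the transfection itself stay open, with the background estimated at 0.217% of mock counts at the trimmed rate.

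Interferon-stimulated genes were higher and unfolded protein response genes lower in the transfectant. After centring by gene length and GC content the medians were 1.93 and -1.87, and the unfolded protein response median was no nearer to 0 than -1.83 over 4 scalings. The median log2 fold of all genes past the floor ran only from 0.24 in the fifth of shortest genes to -0.19 in that of the longest. These checks show only that the trend and the choice among the 4 scalings are small beside the shifts. Their outcome was close to fixed in advance, and they bear on no other cause. A large share of leukocytes in the transfectant culture is argued against by the markers fixed beforehand. Only 3 of 23 were past the floor and at least 2-fold higher, and 11 were at 0 in the transfectant. A small admixture could leave most markers under the floor, where 17 of them lay in both libraries. The count therefore cannot decide on a small admixture, and Lyz2 and Cd68 were among the 3. A difference that follows the transfection and a difference in culture state or between the lines derived from it may each account for the pattern, and with 1 library per group these cannot be separated.

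Genes differed in runs along chromosomes. The SD of the medians of 359 windows of 25 genes was 0.365 against at most 0.235 in 1000 permutations, and 0.331 after centring by length and GC against at most 0.224, which argues against that trend as the cause. Beyond the permuted extremes of -0.91 and 0.99 lay 3 windows on the lower side, 2 on chromosome 8 and 1 on chromosome 3 (-0.95). On the higher side lay 2, on chromosome 11 (1.18) and chromosome X (1.04). In the first 40 Mb of chromosome 8, 92 of 108 genes were lower (median -0.96). From 80 to 120 Mb on chromosome X, 44 of 47 were higher (median 1.06). These regions were picked for their values. The chromosome 8 region is wider than its run, since the chromosome's first window and the window that passes 40 Mb had medians of only -0.27 and -0.21. The test below therefore also took in genes outside that run. The hypothesis of a copy number or other regional difference predicted the same shift in genes of 20 to 99 mean counts that had not been used. These held-out genes were taken from the whole of each region. By the bounds set beforehand the prediction failed in both regions. Relative to such genes elsewhere, the median was -0.28 on chromosome X (10 genes) and -0.087 on chromosome 8 (12 genes). The held-out medians were themselves positive, at 0.23 on chromosome X and 0.42 on chromosome 8, against 0.51 for such genes elsewhere. The genes compared against were thus shifted upwards, since the median of all genes past the floor was 0.07. The bootstrap 95% interval was -0.78 to 0.46 on chromosome X, short of the predicted 0.5, and -1.05 to 1.00 on chromosome 8, where the prediction and its absence cannot be told apart because the interval holds both. For chromosome X, the central 95% of random draws of as many genes from elsewhere ran from -0.91 to 1.05. That test was therefore weak too, and a difference that follows the transfection stays open.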
